A study of Mus musculus with 21 samples.

How the data were processed

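Isolated islets of C57BL/6 mice were sequenced uncultured or after 3 or 12 days in wells coated with laminin-521, laminin-421 or laminin-111 at 5 µg/cm2, with 20 islets per well. According to the labels, replicates A, B and C of a group are separate wells, and RNA was isolated with a Norgen single cell kit. Libraries were made from 2 ng of RNA with the NuGEN Ovation kit for single cells and sequenced as paired 75 bp reads on a HiSeq2000 in 3 batches, and the labels do not assign libraries to batches. Whether the wells or the uncultured replicates came from separate mice is not stated, so the p-values may measure technical spread in part.

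The authors deposited a table of raw counts and a table of FPKM values (fragment counts scaled to transcript length and library size), each with 1 column per library, and neither pools replicates. Per the submitters' processing notes, reads were aligned with STAR 2.5.1b to mm10, and FastQC and Cufflinks 2.1.1 were used. The counting tool, annotation release, strand setting and any filter are not given in the sources used here. Reads shared between paralogs or pseudogenes (Ins1 and Ins2, Krt8, Krt18 and their copies, the acinar protease and lipase families, and genes of the major histocompatibility complex) therefore leave the counts of such genes uncertain. The tables hold 46977 Ensembl gene IDs, of which 46484 were paired with a symbol, and 20 genes with 22 missing cells were left out, leaving 46957. Counts were whole numbers, but 434 cells held a count of 0 beside an FPKM above 0, and all 13 counts of 7 or more digits ended in 0, so the deposited whole numbers can be rounded estimates. Positions are those of GENCODE M21 on GRCm38 (mm10), for the gene IDs in the tables.

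Library totals ran from 10503073 to 24512926 counts, so that a floor of 3 counts corresponds to 0.122 to 0.278 CPM. Reads carry no molecular identifiers here, so floors cover counting error only. Counts were filtered with filterByExpr (minimum count 10, minimum total 15), which left 19193 genes, and scaled with TMM factors (0.864 to 1.07). All 21 libraries entered 1 quasi-likelihood fit with robust prior in edgeR 4.0.16 (R 4.3.3) with the 7 groups as the only term and 14 residual degrees of freedom. The common biological coefficient of variation was 0.590, and the median per gene 0.413. Each of the 16 comparisons was a contrast of that fit: days 3 and 12 against day 0 and against each other with coatings averaged, the 3 coating pairs at each day, each coating at each day against day 0, and the laminin by day interaction. A gene was called at a Benjamini-Hochberg adjusted p of at most 0.05, and is said to have risen, fallen or changed only then. The SE of a log2 fold change is its size divided by the square root of the F statistic. Folds are not given for genes at 0 in every library of a group, for which only CPM are printed.

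A total of 34 gene lists was fixed beforehand, for islet cell types (beta, alpha, delta, PP and epsilon), beta cell dedifferentiation, disallowed genes and granules. Others were for acinar, ductal, endothelial, fibroblast and stellate, macrophage and leukocyte, Schwann and neural, and erythroid cells, for proliferation, matrix, adhesion, YAP and TEAD, mesenchymal transition, TGF-beta and Wnt. The rest were for stress, interferon, inflammation, immediate early, metabolic, mitochondrial, ribosomal, apoptosis, senescence and glucose responsive genes. The erythroid list had 4 tested members, fewer than the minimum of 5, and was not tested. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists of a comparison, and members were also counted with p adjusted over the list alone. List calls are given in the report with the p obtained with a correlation estimated per list. A list called at the preset correlation is reported as lost where its adjusted p was above 0.05 with the estimated correlation. List medians use fitted values, and where members were at 0 in a whole group the median was recomputed with these set to their bound from 3 counts. The share of counts taken by gene classes was compared between groups by two-sided exact permutation tests, adjusted over all 77 such tests.

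The comparisons, tests, lists, alternatives and the rule for naming genes were set before the data were examined, except where the text says otherwise. Named for each comparison were Ins1, Ins2, Gcg, Sst, Ppy, Pdx1, Mafa, Nkx6-1, Slc2a2, Ucn3 and Mki67. To these were added the 8 largest rises and 8 largest falls among called genes with a mean of at least 8 CPM and no overlap between sides, and up to 4 members with the smallest p of each list that was called or had at least 25% of its members called. Predicted genes, clone names and genes of mitochondrial DNA were left out of the second part. The text names a part of these genes, fewer for the comparisons of single coatings with day 0, and the choice among them was made after their values were seen; some genes are not reported here.

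The alternatives were DESeq2 1.42.0, median-of-ratios scaling (RLE), library totals alone, no low-count filter, at least 10 CPM in 3 libraries, mitochondrial, hormone and acinar genes left out, and the replicate letter as a block. Further ones were limma-trend on the authors' FPKM values (at least 1 in 3 libraries, pseudocount 1 or 0.1), only the libraries compared, each library left out in turn, an estimated correlation or fry for lists, and shares without mitochondrial genes. After the data were seen, fits without 3 libraries that stood apart, with replicate C as the only uncultured library, and tests of list-level differences between coatings and of gene families were added. The 3 libraries that stood apart were uncultured replicate A, replicate C on laminin-421 at day 3 and replicate B on laminin-521 at day 12. Whether replicate letters pair the libraries was checked by correlating their deviations from the group means, using genes with a mean log2 CPM of at least 3. Over 63 pairs with the same letter the median correlation was 0.0467, with 21 over 0.1, and over 126 pairs with different letters it was −0.0264. Deviations from a group mean cancel within the group, so these values are tied and are not separate evidence. Of the libraries 12 of 21 were closest to their own letter. All 3 same-letter pairs (A, B and C) lay over 0.1 for laminin-521 and laminin-421 at day 12 (0.209, 0.291 and 0.257; different letters −0.188 to −0.0514) and for laminin-111 at days 3 and 12 (0.241, 0.160 and 0.115), and in no other pair of groups. In a check chosen after the data were seen, 729 of 46656 orders of the letters within groups gave a mean same-letter correlation as high (share 0.0156), so the letters pair the libraries in part, and the labels do not say what a letter shares. The pipeline was tested on simulated data, with negative binomial counts at the dispersions of the fit and 200 changed genes at folds of 2, 4 and 8. Between day 3 and day 0 edgeR recovered 30.2%, 54.5% and 65.1% of these, with 9 false among 105 calls, and between laminin-521 and laminin-111 at day 12 27.9%, 43.5% and 60.9%, with 3 false among 86. DESeq2 made 46 false among 156 and 35 among 133 calls in the same comparisons. For the interaction edgeR recovered 10.8%, 51.5% and 50.8%. For lists, a simulated changed list was called in each of 3 comparisons and 0 of 33 unchanged lists. The simulated genes varied independently, the unchanged lists were drawn at random, and only the preset correlation was used. This simulation therefore cannot show false list calls that come from correlated members.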

Results

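RNA was sequenced from isolated pancreatic islets of C57BL/6 mice that were either left uncultured (day 0) or kept for 3 or 12 days in wells coated with laminin-521, laminin-421 or laminin-111. Laminins are the trimeric glycoproteins of basement membranes, and the numbers name the alpha, beta and gamma chains. The 21 libraries fell into 7 groups of 3, namely the uncultured islets and each coating at each of the 2 culture days. Total counts per library ran from 10503073 to 24512926, and between 16206 and 20476 genes were detected. After the low-count filter, 19193 genes were tested. Fold changes are log2 values ± the standard error (SE), and normalised counts are CPM (TMM-scaled counts relative to library size) ± SD. The first principal component took 32.9% of the variance and separated the uncultured from the cultured islets.

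The comparison of day 3 with day 0 addressed how the islet transcriptome changed on moving into culture, averaged over the 3 coatings. Pdx1, Mafa and Nkx6-1 were higher after 3 days, acinar enzyme transcripts had largely gone, and stress, interferon and immediate early genes were lower. Pdx1, a master regulator of pancreas and beta cells (ENSMUSG00000029644, chromosome 5, 147269959 to 147275848, plus strand on GRCm38), rose to 196 ± 27.5 against 82.3 ± 19.3 CPM (n = 9 and 3; log2 fold change 1.25 ± 0.15, adjusted p = 3.62e-08). Mafa, an activator of the insulin genes, rose by 1.27 ± 0.18, adjusted p = 1.77e-06, and Nkx6-1, which maintains beta cell identity, by 1.14 ± 0.14, adjusted p = 4.64e-08. The transcripts of insulin itself did not pass the test: Ins1 (ENSMUSG00000035804, chromosome 19, 52264297 to 52265476, plus strand) stood at 19782 ± 4571 against 23387 ± 6367 CPM (−0.24 ± 0.25, adjusted p = 0.571) and Ins2 at −0.22 ± 0.22, adjusted p = 0.553.

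Among endocrine genes, 16 of 28 beta cell identity genes rose and 3 fell, also when adjusted over the list alone, with a median of 0.56 (adjusted p = 0.0302 with an estimated correlation). Trpm5, a cation channel of stimulated secretion, rose by 1.99 ± 0.17, adjusted p = 1.02e-10, and Rfx6, a transcription factor of islet development, by 1.90 ± 0.17, adjusted p = 1.68e-10. The glucose transporter Slc2a2 rose by 1.18 ± 0.14, adjusted p = 1.85e-07, the fatty acid receptor Ffar1 by 1.22 ± 0.13 and the incretin receptor Glp1r by 1.00 ± 0.11. Of 29 genes of the insulin granule and exocytosis, 5 rose and 9 fell (7 and 9 adjusted over the list alone), and the list as a whole was not called. Its granule protein Vgf fell by 2.75 ± 0.27, adjusted p = 3.74e-08. In the alpha cell list 6 of 16 genes rose and 2 fell. The cationic amino acid transporter Slc7a2 (ENSMUSG00000031596, chromosome 8, 40862396 to 40922308, plus strand) rose by 2.01 ± 0.17, adjusted p = 9.53e-10, and the peptidase Dpp4 by 1.15 ± 0.20. Glucagon (Gcg) stood at 0.52 ± 0.21, adjusted p = 0.102, and somatostatin (Sst) at 0.16 ± 0.15, adjusted p = 0.493. In the delta cell list 2 of 10 rose and in the PP and epsilon cell list 2 of 6, and neither list was called. The proliferation marker Mki67 stood at 12.3 ± 6.65 against 14.2 ± 5.85 CPM (−0.25 ± 0.45, adjusted p = 0.777), and 1 of 39 proliferation genes rose and 1 fell.

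Transcripts of the exocrine pancreas fell most. All acinar list genes together held 5.89 ± 5.12% of counts at day 0 and 0.0714 ± 0.108% at day 3 (two-sided exact permutation p = 0.00455, the smallest 3 against 9 can give; adjusted p = 0.0389). The uncultured replicates A, B and C differed, at 11.5%, 4.81% and 1.40%, and replicate C on laminin-421 held the most among cultured libraries, at 0.351%. Of 29 acinar genes 27 fell (28 adjusted over the list alone), with a median of −8.40, or −8.05 with members at 0 in a whole group set to their bound, and adjusted p = 0.110 with an estimated correlation. Pancreatic lipase (Pnlip) went from 11979 to 4.60 CPM (−12.59 ± 1.41, adjusted p = 2.55e-05), the bile salt lipase Cel changed by −12.22 ± 1.11, adjusted p = 9.78e-07, and the elastase Cela1 by −8.42 ± 0.81, adjusted p = 1.77e-06. Ductal list genes fell in 8 of 17 cases (9 over the list alone) and rose in 1 (adjusted p = 0.000296 with an estimated correlation). The tight junction protein Cldn4 changed from 684 to 74.3 CPM (−3.21 ± 0.13, adjusted p = 2.08e-20), and the epithelial keratins Krt8 and Krt18 changed by −4.15 ± 0.21 and −2.82 ± 0.12. Endothelial genes fell in 8 of 22 (9 over the list alone; adjusted p = 0.0891 with an estimated correlation). Plvap, of fenestrated capillaries, changed by −2.46 ± 0.41, adjusted p = 9.43e-05 and the junction protein Pecam1 by −1.67 ± 0.32, adjusted p = 0.000138. In the macrophage and leukocyte list 8 of 25 rose and 4 fell, and the list was not called. Its 4 fallen members were antigen presentation genes of class II, of which the invariant chain Cd74 fell by 3.08 ± 0.25, adjusted p = 5.96e-12. The largest rise by the naming rule was that of Gpnmb (ENSMUSG00000029816, chromosome 6, 49036546 to 49070929, plus strand), a glycoprotein of activated macrophages, at 13.1 ± 10.3 against 0.0622 ± 0.108 CPM (adjusted p = 0.00131). Fibroblast and stellate cell genes rose in 6 of 30 (adjusted p = 0.686 with an estimated correlation). Fibronectin (Fn1) rose by 4.87 ± 1.04, adjusted p = 0.00316.

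**Figure D1:**
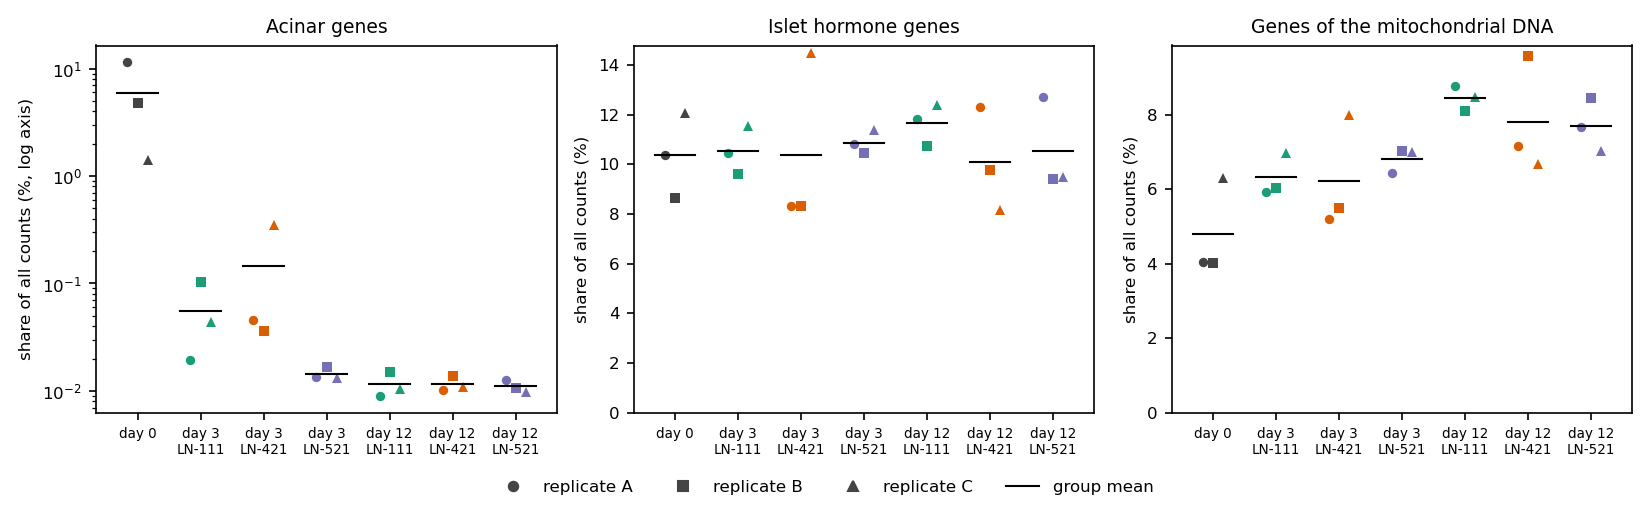
Share of all counts in each of the 21 libraries taken by acinar genes (percent, logarithmic axis), hormone genes (percent) and genes encoded in mitochondrial DNA, rRNA included (percent), by group; points are libraries and lines are group means. Acinar genes held 1.40% to 11.5% in the uncultured libraries and at most 0.351% in the cultured libraries.

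Stress and signalling genes fell together on the change from uncultured to day 3 islets. Of 28 interferon response genes 25 fell (27 adjusted over the list alone), with a median of −3.33 (adjusted p = 2.03e-05 with an estimated correlation). The unfolded protein response list had 22 of 24 genes lower and 1 higher, also over the list alone, with a median of −1.21 (adjusted p = 0.000123 with an estimated correlation). Hspa5, the main chaperone of the endoplasmic reticulum (ENSMUSG00000026864, chromosome 2, 34771970 to 34777547, plus strand), stood at 996 ± 97.1 against 4850.1 ± 1525 CPM (−2.28 ± 0.12, adjusted p = 1.22e-15). The phosphatase regulator Ppp1r15a, which restores translation after stress, changed by −2.82 ± 0.17 and the folding factor Creld2 by −2.03 ± 0.15. Immediate early genes fell in 19 of 23 (20 over the list alone), with a median of −2.76 (adjusted p = 0.000643 with an estimated correlation), including the AP-1 subunits Jund at −2.76 ± 0.13, adjusted p = 7.20e-18 and Jun at −3.55 ± 0.24. Inflammation and chemokine genes fell in 12 of 21 (14 over the list alone, where 1 rose; adjusted p = 0.00585 with an estimated correlation). The NF-kB inhibitor Nfkbia changed by −2.98 ± 0.19, adjusted p = 1.51e-14. Cholesterol synthesis genes fell in 13 of 22, also over the list alone (adjusted p = 0.00465 with an estimated correlation). The sterol sensor partner Insig1 changed by −1.51 ± 0.15 and the enzyme Msmo1 by −1.43 ± 0.15. Apoptosis and p53 genes fell in 10 of 23 and rose in 1 (10 and 2 over the list alone; adjusted p = 0.00465 with an estimated correlation). The cell cycle inhibitor Cdkn1a changed by −2.44 ± 0.22, adjusted p = 4.30e-10 and the survival protein Mcl1 by −1.37 ± 0.11. Oxidative stress and NRF2 genes fell in 10 of 19 and rose in 1 (10 and 2 over the list alone; adjusted p = 0.0111 with an estimated correlation). The sulfiredoxin Srxn1 changed by −2.01 ± 0.13 and the autophagy receptor Sqstm1 by −1.66 ± 0.12.

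Part of the adhesion genes fell at day 3 as well. Laminin receptor and adhesion genes fell in 10 of 29 (13 over the list alone, where 1 rose; adjusted p = 0.0874 with an estimated correlation). The focal adhesion protein vinculin (Vcl) changed by −3.05 ± 0.25, adjusted p = 4.89e-08 and the integrin subunit Itgav by −1.02 ± 0.12. YAP and TEAD targets fell in 5 of 18 and rose in 1 (7 and 1 over the list alone; adjusted p = 0.155 with an estimated correlation), including the transcription factor Tead1 itself at −1.40 ± 0.11. Of the 27 matrix and basement membrane genes 2 rose and 6 fell without a call for the list. The matrix glycoprotein thrombospondin 1 (Thbs1; ENSMUSG00000040152, chromosome 2, 118111876 to 118127133, plus strand) stood at 16.2 ± 4.55 against 174 ± 25.8 CPM (−3.42 ± 0.45, adjusted p = 5.04e-05). The remaining lists were not called at day 3. Genes of TGF-beta and BMP signalling numbered 1 risen and 3 fallen of 18, disallowed genes of beta cells 0 and 2 of 28, and dedifferentiation and progenitor genes 3 and 2 of 13. Mesenchymal transition genes numbered 1 risen and 1 fallen of 18, Schwann and neural genes 1 and 1 of 16, and Wnt pathway genes 3 and 1 of 18. Hypoxia and glycolysis genes numbered 4 risen and 2 fallen of 26, nuclear respiratory chain genes 3 and 2 of 34, and cytosolic ribosomal protein genes 0 and 1 of 40. Glucose responsive genes numbered 3 risen and 4 fallen of 14, senescence genes 2 and 1 of 13, and genes of mitochondrial DNA 1 and 4 of 12. Median, mean and test differed in sign in 9 of these or the preceding uncalled lists, namely the alpha, delta, PP and epsilon, granule, dedifferentiation, mesenchymal transition, glucose responsive, Wnt and mitochondrial DNA lists.

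In all, 4191 of 19193 genes changed between day 0 and day 3, 1831 higher and 2360 lower, and in 19.6% of genes the sides did not overlap, against 0.909% by chance. For each gene named here as risen or fallen, all 9 cultured libraries lay beyond all 3 uncultured libraries, which the naming rule required of the largest rises and falls. With scaling by library totals alone the median of all genes moved by 0.20 and the split became 2966 higher and 1646 lower, with Gcg then past the threshold at 0.72 (adjusted p = 0.0249). Gcg also passed it without the low-count filter, with genes of at least 10 CPM and with only the libraries compared (adjusted p = 0.000465, 0.0372 and 0.0251). With the authors' FPKM values Mafa and Nkx6-1 missed the threshold (adjusted p = 0.0643 and 0.0714; 3.54e-11 to 0.0645 and 4.46e-15 to 0.0726 over all alternatives). Without replicate C of laminin-421 Ins2 passed it at −0.40 (adjusted p = 0.0360). With replicate C as the only uncultured library Gpnmb and Fn1 missed it (adjusted p = 0.116 and 0.150).

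**Figure D2:**
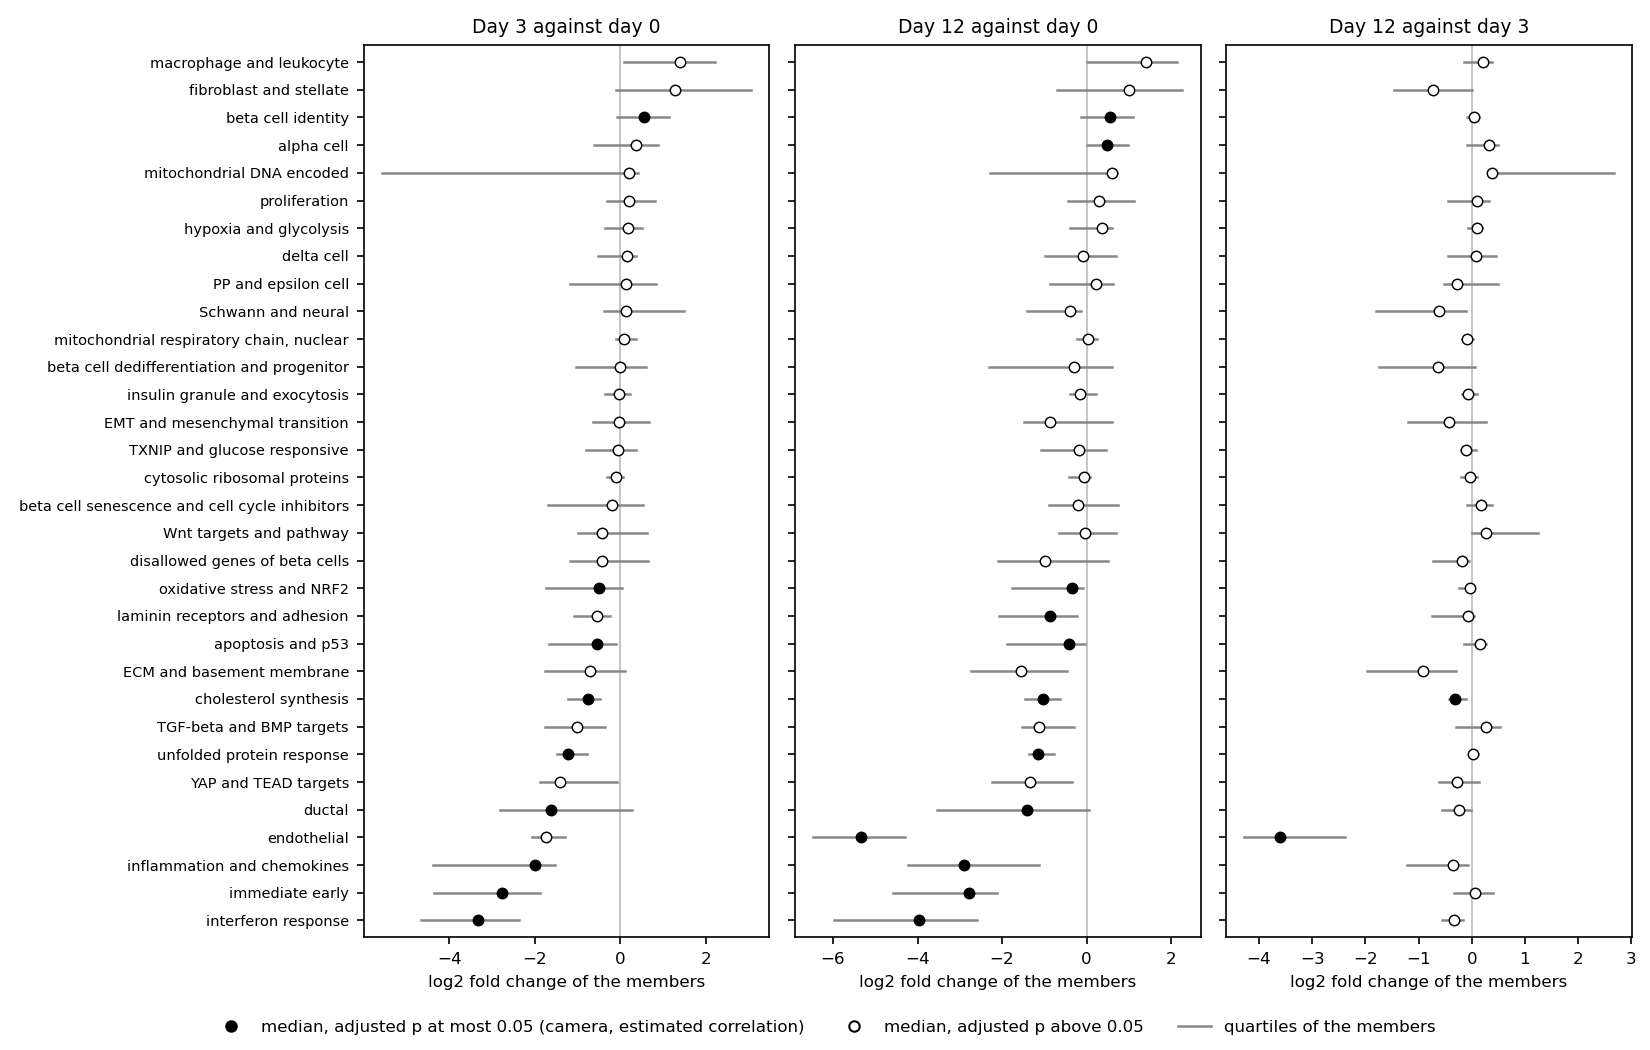
Median log2 fold change (points) and quartiles (bars) of the tested members of 32 gene lists for day 3 against day 0, day 12 against day 0 and day 12 against day 3; filled points are lists with an adjusted p of at most 0.05 with an estimated correlation. Values are fitted ones, and the acinar list is left out because most of its members were at 0 in a whole group at day 12; the interferon response median was −3.33 at day 3 and −3.97 at day 12 against day 0.

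The comparison of day 12 with day 0 asked how islets stood after the longer culture. The rise of Pdx1, Mafa and Nkx6-1 and the fall of stress, interferon and immediate early genes held at day 12, and endothelial transcripts had nearly gone. Pdx1 stood at 234 ± 51.4 against 82.3 ± 19.3 CPM (n = 9 and 3; 1.49 ± 0.15, adjusted p = 1.07e-09), and Mafa, Nkx6-1 and Slc2a2 rose by 1.36 ± 0.18, 1.30 ± 0.14 and 1.09 ± 0.14. Ins1 fell by 0.72 ± 0.24, adjusted p = 0.0392 and was lower in 8 of 9 cultured libraries (14203 ± 3204 against 23387 ± 6367 CPM), while Ins2 stood at −0.06 ± 0.22, adjusted p = 0.898. Gcg rose by 0.89 ± 0.22, adjusted p = 0.00613 and Sst by 0.48 ± 0.15, adjusted p = 0.0162, each in 8 of 9 libraries.

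Beta cell identity genes rose in 16 of 28 and fell in 3, also over the list alone, with a median of 0.56 (adjusted p = 0.0294 with an estimated correlation). Alpha cell genes rose in 7 of 16 and fell in 3 (10 and 3 adjusted over the list alone; adjusted p = 0.0457 with an estimated correlation). Slc7a2 rose by 2.16 ± 0.17, adjusted p = 2.77e-10. The vasopressin receptor Avpr1b, among the largest rises, went from 3.60 to 28.1 CPM (2.94 ± 0.30, adjusted p = 2.11e-09). Gpnmb stood at 40.5 ± 31.4 against 0.0622 ± 0.108 CPM (adjusted p = 0.000218). Mki67 stood at 0.29 ± 0.46, adjusted p = 0.724, and 2 of 39 proliferation genes rose.

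Interferon response genes fell in 28 of 28, with a median of −3.97 (adjusted p = 4.06e-05 with an estimated correlation). The unfolded protein response list had 22 of 24 lower (22 lower and 1 higher over the list alone; adjusted p = 0.000486 with an estimated correlation). Hspa5 changed by −2.30 ± 0.12, adjusted p = 1.07e-15. Immediate early genes fell in 20 of 23 (22 over the list alone; adjusted p = 0.00112 with an estimated correlation). Jund changed by −2.19 ± 0.13, adjusted p = 4.52e-15. Inflammation genes fell in 13 of 21 (14 over the list alone; adjusted p = 0.00335 with an estimated correlation). Nfkbia changed by −3.34 ± 0.19. Cholesterol synthesis genes fell in 16 of 22 (18 over the list alone; adjusted p = 0.000609 with an estimated correlation). Hmgcs1, which makes its precursor, changed by −1.44 ± 0.14 and Insig1 by −1.71 ± 0.15. Oxidative stress genes fell in 8 of 19 and rose in 1 (adjusted p = 0.0184 with an estimated correlation), and apoptosis and p53 genes fell in 10 of 23 and rose in 2 (adjusted p = 0.0218 with an estimated correlation). Cdkn1a changed by −2.05 ± 0.22.

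Endothelial genes fell in 19 of 22 (21 over the list alone), with a median of −5.35, or −4.80 with members at 0 in a whole group set to their bound (adjusted p = 0.000596 with an estimated correlation). Pecam1 changed by −4.40 ± 0.32, adjusted p = 6.66e-13, Plvap by −6.67 ± 0.47, adjusted p = 2.39e-10, and the endothelial transcription factor Erg stood at 0.206 ± 0.385 against 17.3 ± 4.16 CPM (adjusted p = 6.81e-11). Acinar genes fell in 29 of 29 (adjusted p = 0.0519 with an estimated correlation), among them the elastase Cela2a at 0.821 ± 2.13 against 8209 ± 8472 CPM and the carboxypeptidase Cpa1 at 0.490 ± 1.12 against 4795 ± 4137 CPM. Ductal genes fell in 8 of 17 and rose in 1, also over the list alone (adjusted p = 0.000486 with an estimated correlation). Cldn4 changed by −3.39 ± 0.13, adjusted p = 3.56e-21. Laminin receptor and adhesion genes fell in 17 of 29 and rose in 2 (19 and 3 over the list alone; adjusted p = 0.0294 with an estimated correlation). Vcl changed by −3.23 ± 0.25. Matrix and basement membrane genes fell in 14 of 27 and rose in 2 (16 and 2 over the list alone; adjusted p = 0.125 with an estimated correlation). YAP and TEAD targets (adjusted p = 0.0904 with an estimated correlation) fell in 6 of 18 and rose in 1, and disallowed genes of beta cells fell in 6 of 28 (adjusted p = 0.654 with an estimated correlation).

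Genes of mitochondrial DNA rose in 5 of 12 (6 over the list alone; adjusted p = 0.570 with an estimated correlation), where the median was 0.60 and the mean −0.62. All genes of mitochondrial DNA, rRNA included, held 4.79 ± 1.30% of counts at day 0, 6.46 ± 0.885% at day 3 and 8.0 ± 0.939% at day 12 (day 12 against day 0, two-sided exact permutation p = 0.00455, the smallest possible; adjusted p = 0.0389). Most of this was mitochondrial rRNA, at 3.23 ± 0.958%, 4.17 ± 0.585% and 5.07 ± 0.656% (day 12 against day 0, two-sided exact permutation p = 0.0136, adjusted p = 0.0954). The cytochrome oxidase subunit mt-Co1 rose by 0.66 ± 0.13, adjusted p = 0.000279 and the complex I subunit mt-Nd4 by 0.74 ± 0.14. Hypoxia and glycolysis genes, not called as a list, rose in 6 of 26 and fell in 2. The pyruvate dehydrogenase kinase Pdk1 rose by 1.26 ± 0.20, adjusted p = 9.61e-06.

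Altogether 4793 genes changed between day 0 and day 12, 2044 higher and 2749 lower, and 16.8% of genes did not overlap, against 0.909% by chance. Apart from Ins1, Gcg and Sst, all 9 cultured libraries lay beyond all 3 uncultured ones for each gene named as risen or fallen. The naming rule required this of the largest rises and falls. The call of Ins1 was lost without uncultured replicate A or C, or replicate B on laminin-111, C on laminin-421 or C on laminin-521 at day 12 (adjusted p = 0.0986, 0.216, 0.0606, 0.0536 and 0.0541), with the replicate letter as a block (adjusted p = 0.0566), with library totals (adjusted p = 0.0879) and with FPKM (adjusted p = 0.247; 1.09e-08 to 0.285 over all alternatives). That of Gcg was lost without uncultured replicate A (adjusted p = 0.0552). The call of Sst was lost without A or B (adjusted p = 0.151 and 0.111). With FPKM values the calls of Sst and mt-Co1 were lost (adjusted p = 0.149 and 0.0811), and with a pseudocount of 0.1 that of Gcg too (0.0609). Those of Gcg, Sst, mt-Co1 and mt-Nd4 were lost with replicate C as the only uncultured library (adjusted p = 0.403, 0.618, 0.307 and 0.341).

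**Figure D3:**
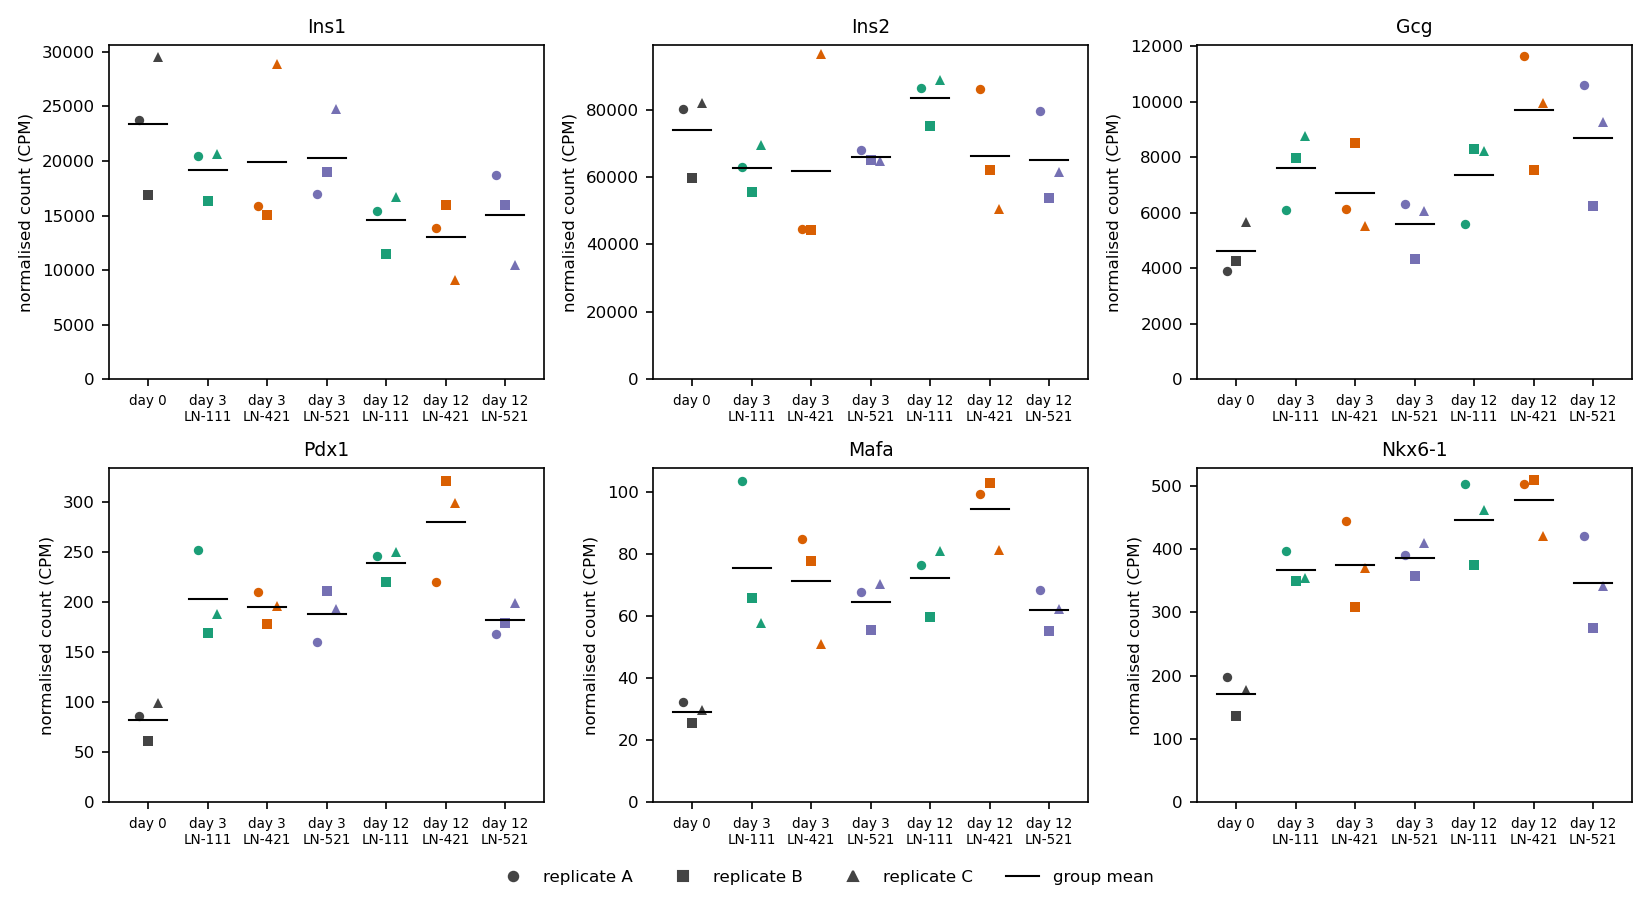
Normalised counts (CPM) of Ins1, Ins2, Gcg, Pdx1, Mafa and Nkx6-1 in each library by group; points are libraries and lines are group means (n = 3). Pdx1 averaged 82.3 CPM in uncultured islets, 196 at day 3 and 234 at day 12.

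The comparison of day 12 with day 3 asked what went on changing within culture, averaged over the coatings. Of the gene lists the endothelial one had the smallest p, with a further loss of its transcripts. Kdr, the main receptor of vascular endothelial growth factor, fell by 4.17 ± 0.40, adjusted p = 2.73e-05, and its relative Flt1 went from 32.2 to 2.01 CPM (−4.29 ± 0.45, adjusted p = 0.000113). The clock output factor Dbp rose by 0.86 ± 0.13, adjusted p = 0.000156 (72.4 ± 15.3 against 39.6 ± 5.97 CPM; n = 9 and 9), its relative Hlf by 0.86 ± 0.18, adjusted p = 0.00534 and the clock repressor Nr1d2 by 0.43 ± 0.09, adjusted p = 0.00700. No list of circadian clock genes was tested, and with FPKM values these 3 calls were lost (adjusted p = 0.0965, 0.0862 and 0.402).

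Endothelial genes fell in 12 of 22 (18 over the list alone), with a median of −3.61, or −3.07 with members at 0 in a whole group set to their bound (adjusted p = 1.61e-05 with an estimated correlation). Pecam1 changed by −2.73 ± 0.27, adjusted p = 1.16e-07, and Plvap by −4.20 ± 0.40, adjusted p = 2.17e-06, lower in 7 of 9 libraries. Outside the list, the endothelin receptor Ednrb changed by −5.78 ± 0.54, adjusted p = 2.78e-05 and the fatty acid carrier Cd36 by −2.19 ± 0.35, adjusted p = 0.00242. The share of counts from endothelial genes was 0.0587 ± 0.00822% at day 0, 0.0184 ± 0.00585% at day 3 and 0.00331 ± 0.00174% at day 12 (day 12 against day 3, two-sided exact permutation p = 4.11e-05, the smallest possible; adjusted p = 0.00317).

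Acinar genes fell further in 6 of 29 (11 over the list alone; adjusted p = 0.0926 with an estimated correlation). The chymotrypsinogen Ctrb1 stood at 1.00 ± 2.5 against 197 ± 355 CPM and the lipase relative Pnliprp1 at 0.316 ± 0.676 against 81.5 ± 136 CPM, each lower in 8 of 9 libraries. Replicate C on laminin-421 held the most acinar RNA at day 3 (0.351% of counts). Cholesterol synthesis genes fell in 3 of 22 (6 over the list alone; adjusted p = 0.0292 with an estimated correlation). Alpha cell genes rose in 1 of 16 and fell in 1 (7 and 1 over the list alone; adjusted p = 0.0517 with an estimated correlation). The risen member was transthyretin (Ttr) at 0.91 ± 0.14, adjusted p = 0.00154, higher in 8 of 9 libraries, and the fallen member Dpp4 at −0.68 ± 0.13, adjusted p = 0.00356.

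The hormones stood at −0.48 ± 0.18, adjusted p = 0.243 for Ins1, 0.38 ± 0.15, adjusted p = 0.267 for Gcg and 0.32 ± 0.10, adjusted p = 0.125 for Sst, and the transcription factors at 0.24 ± 0.10, adjusted p = 0.259 for Pdx1 and 0.10 ± 0.12 for Mafa. Without the low-count filter Ins1, Gcg and Sst passed the threshold (adjusted p = 1.96e-06, 0.00140 and 0.0217). As a share of counts Ins1 went from 2.03 ± 0.425% to 1.43 ± 0.326% (two-sided exact permutation p = 0.00247, adjusted p = 0.0389), and all hormone genes from 10.6 ± 1.87% to 10.8 ± 1.63% (p = 0.846 by the same permutation test). Matrix genes fell in 3 of 27 (14 fell and 1 rose over the list alone; adjusted p = 0.0517 with an estimated correlation), and the adhesion receptor of hyaluronan, Cd44, in the mesenchymal transition list (adjusted p = 0.282 with an estimated correlation), changed by −0.74 ± 0.12, adjusted p = 0.000198. Interferon response genes fell in 3 of 28 (6 over the list alone; adjusted p = 0.0511 with an estimated correlation), ductal genes in 1 of 17 (adjusted p = 0.0511 with an estimated correlation) and fibroblast genes in 1 of 30 (adjusted p = 0.424 with an estimated correlation). Genes of mitochondrial DNA rose in 1 of 12 (3 over the list alone; adjusted p = 0.180 with an estimated correlation), namely mt-Co1 at 0.46 ± 0.09, adjusted p = 0.00376, higher in 7 of 9 libraries.

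In all, 270 genes changed between day 3 and day 12, 67 higher and 203 lower, and 0.302% of genes did not overlap, against 0.00411% by chance. Where no number of libraries is given, all 9 libraries of day 12 lay beyond all 9 of day 3 for a gene named as risen or fallen. The naming rule required this of the largest rises and falls. The neuronal calcium sensor Kcnip1 (0.46 ± 0.09) and the membrane protein Itm2c (0.36 ± 0.08) rose as well, and with FPKM values the calls of these and of mt-Co1 were lost (adjusted p = 0.0768, 0.285 and 0.311). Without replicate C of laminin-421 at day 3 Sst passed the threshold at 0.38 (adjusted p = 0.0430).

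**Figure D4:**
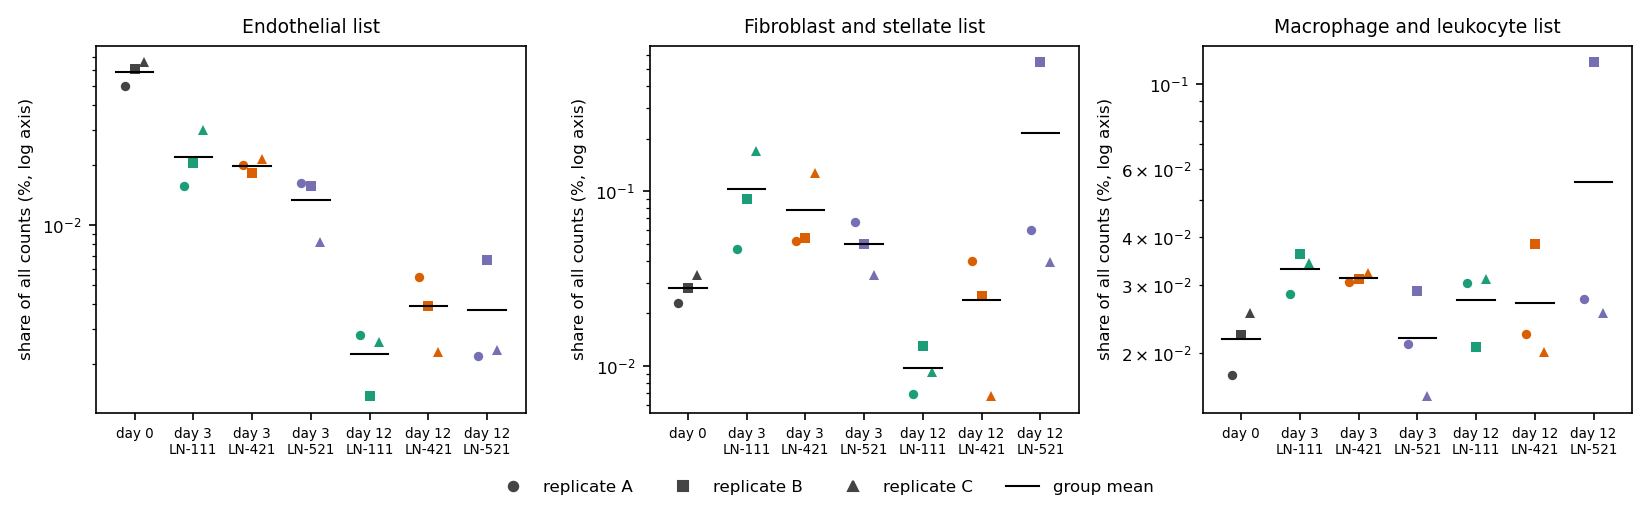
Share of all counts (percent, logarithmic axis) taken by endothelial, fibroblast and macrophage list genes in each library by group; points are libraries and lines are group means (n = 3). Endothelial genes averaged 0.0587% in uncultured islets and 0.00331% at day 12, and fibroblast genes reached 0.549% in replicate B on laminin-521 at day 12.

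Whether laminin-521 acted unlike the other coatings was addressed first at day 3. No gene passed the edgeR test between laminin-521 and laminin-111, between laminin-521 and laminin-421, or between laminin-421 and laminin-111 at day 3, where 513, 514 and 354 genes had an unadjusted p under 0.05 and DESeq2 called 8, 9 and 0. Pdx1 stood at −0.11 ± 0.17 on laminin-521 against laminin-111, −0.05 ± 0.17 against laminin-421 and −0.06 ± 0.17 for laminin-421 against laminin-111, and Mafa at −0.23 ± 0.21, −0.14 ± 0.21 and −0.09 ± 0.21. Ins1 stood at 0.08 ± 0.31, 0.02 ± 0.31 and 0.06 ± 0.31 in the same order, Ins2 at 0.07 ± 0.27, 0.09 ± 0.27 and −0.02 ± 0.27, and Nkx6-1 at 0.07 ± 0.15 against laminin-111. Among list members with the smallest p, the basement membrane proteoglycan agrin (Agrn) stood at −0.84 ± 0.32 against laminin-111 (12.8 ± 2.55 against 22.9 ± 4.46 CPM) and −1.05 ± 0.32 against laminin-421. The class II gene H2-Eb1 stood at −1.73 ± 0.54 against laminin-111, and Cd74 and the class I gene H2-D1 at −1.12 ± 0.35 and −0.37 ± 0.14 against laminin-421. With a preset correlation 13 lists were called against laminin-111 and 14 against laminin-421, and 4 between laminin-421 and laminin-111, but none with an estimated correlation (adjusted p from 0.365, 0.118 and 0.397 upwards). The macrophage list median was −0.86 against laminin-111 (adjusted p = 0.365 with an estimated correlation) and −0.69 against laminin-421 (adjusted p = 0.290 with an estimated correlation). The acinar list median was −3.30 and −5.17, or −3.24 and −5.05 with members at 0 in a whole group set to their bound (adjusted p = 0.365 and 0.290 with an estimated correlation). Acinar genes took 0.0144 ± 0.00188% of counts on laminin-521, 0.0554 ± 0.0429% on laminin-111 and 0.144 ± 0.179% on laminin-421 (exact permutation p = 0.1 for both, the smallest that 3 against 3 can give). The sides did not overlap in 9.93%, 9.94% and 7.99% of genes, against 10% by chance. With the replicate letter as a block 2 genes each were called for laminin-521 against laminin-111 and against laminin-421.

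At day 12, 8 genes differed between laminin-521 and laminin-111, all higher on laminin-521, and they included genes of matrix, contractility and the cytoskeleton. Thbs1 stood at 292 ± 294 against 10.2 ± 6.12 CPM (n = 3 and 3; 4.82 ± 0.71, adjusted p = 0.0285), and the fibril-associated collagen Col12a1 at 38.1 ± 42.6 against 2.33 ± 1.52 CPM (4.02 ± 0.72, adjusted p = 0.0285). The myosin light chain kinase Mylk differed by 5.32 ± 0.97, adjusted p = 0.0439, the cytoskeletal regulator Dpysl3 by 4.31 ± 0.77, adjusted p = 0.0285 and the cytoskeletal pseudokinase Peak1 by 2.14 ± 0.40, adjusted p = 0.0361. Each of these 5 genes was higher in 3 of 3 libraries, as the naming rule required of the largest rises. This carries little weight alone, since 10.8% of all genes did not overlap between the sides, against 10% by chance. With the replicate letter as a block 4 genes were called, all among the 8, and Thbs1, Mylk, Col12a1 and Peak1 missed the threshold (adjusted p = 0.0718, 0.0900, 0.0900 and 0.0733), while Dpysl3 kept its call (0.0348). With FPKM values Mylk, Dpysl3, Col12a1 and Peak1 lost theirs (adjusted p = 0.598, 0.649, 0.171 and 0.590), and with only the 6 libraries compared all 5 did (0.0944, 0.130, 0.125, 0.130 and 0.205 for Thbs1, Mylk, Dpysl3, Col12a1 and Peak1). Without the 3 libraries that stood apart Mylk, Dpysl3, Col12a1 and Peak1 lost theirs as well (0.477, 0.346, 0.571 and 0.518), and with RLE factors Mylk did (0.0505). The beta cell genes named for every comparison did not pass the edgeR test. Pdx1 stood at −0.39 ± 0.17, adjusted p = 0.643, Mafa at −0.22 ± 0.21, Nkx6-1 at −0.37 ± 0.15, Slc2a2 at −0.40 ± 0.16, Ins1 at 0.05 ± 0.31 and Ins2 at −0.36 ± 0.27. Of 15 lists called with a preset correlation, 6 held with an estimated correlation, and all 6 were higher on laminin-521. The fibroblast and stellate list had a median of 4.41 (adjusted p = 0.0201 with an estimated correlation), with 25 of 30 genes higher when adjusted over the list alone and 0 over all genes. The matrix protein Sparc stood at 4.32 ± 1.01, adjusted p = 0.216, the fibrillin Fbn1 at 4.86 ± 1.08, adjusted p = 0.180 and the contractile protein Tagln at 3.80 ± 0.94, adjusted p = 0.227, and DESeq2 called all 3. In the simulated data for this comparison, however, 35 of 133 DESeq2 calls were false. The matrix and basement membrane list had a median of 2.91 with 15 of 27 higher over the list alone (adjusted p = 0.0180 with an estimated correlation). The mesenchymal transition list had 2.80 with 10 of 18 (adjusted p = 0.0180 with an estimated correlation) and the YAP and TEAD list 1.68 with 6 of 18 (adjusted p = 0.0123 with an estimated correlation). The YAP target Ccn2 stood at 4.64 ± 1.03, adjusted p = 0.178 and was called by DESeq2. The TGF-beta list had a median of 1.35 with 9 of 18 higher over the list alone (adjusted p = 0.0123 with an estimated correlation), and the laminin receptor and adhesion list 0.36 with 9 of 29 (adjusted p = 0.0201 with an estimated correlation). The fibroblast list took 0.0598%, 0.549% and 0.0392% of counts in replicates A, B and C on laminin-521 and 0.00691 to 0.0130% on laminin-111 (exact permutation p = 0.1, the smallest possible). Replicate B also held the most macrophage RNA, 0.114% of counts. Among lists lost with an estimated correlation, the macrophage median was 1.01 (adjusted p = 0.469 with an estimated correlation), that of disallowed genes 1.31 (adjusted p = 0.272 with an estimated correlation) and that of beta cell identity −0.21 (adjusted p = 0.198 with an estimated correlation).

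The count of 8 between laminin-521 and laminin-111 at day 12 rested on few libraries: it was 2, 2 and 6 without replicates A, B and C on laminin-111, and 14, 3 and 49 without A, B and C on laminin-521. Without replicate B on laminin-521 the adjusted p was 0.455 for Mylk, 0.344 for Dpysl3, 0.546 for Col12a1 and 0.546 for Peak1, while Thbs1 kept its call. Without A, B or C on laminin-111 it was 0.210, 0.134 and 0.116 for Thbs1, 0.392, 0.213 and 0.221 for Mylk, 0.324, 0.213 and 0.116 for Dpysl3, and 0.302, 0.264 and 0.0722 for Peak1. For Col12a1 it was 0.391 without A and 0.243 without B.

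Against laminin-421, 22 genes differed at day 12, all higher on laminin-521. They included Thbs1 (292 ± 294 against 11.2 ± 4.90 CPM; 4.71 ± 0.71, adjusted p = 0.0166), Col12a1 (4.49 ± 0.73, adjusted p = 0.00872), the membrane repair protein Myof (3.17 ± 0.58, adjusted p = 0.0117) and the growth factor Tgfb3 (3.14 ± 0.60, adjusted p = 0.0156). The dynamin Dnm3, a membrane scission protein, stood at 82.6 ± 18.9 against 33.8 ± 5.26 CPM (1.29 ± 0.19, adjusted p = 0.000718). The laminin beta 2 chain (Lamb2), which is part of laminin-521 and laminin-421 protein alike, stood at 11 ± 14.7 against 0.0782 ± 0.0906 CPM (adjusted p = 0.000718). Each of these 6 genes was higher in 3 of 3 libraries, which the naming rule required of the largest rises, and 9.99% of all genes did not overlap, against 10% by chance. Lists moved as against laminin-111 but were lost with an estimated correlation: the fibroblast median was 3.28 (21 of 30 over the list alone; adjusted p = 0.135 with an estimated correlation) and the matrix median 2.72, or 2.5 with members at 0 at their bound (adjusted p = 0.0650 with an estimated correlation). The medians of the YAP and TEAD, TGF-beta and mesenchymal transition lists were 1.65, 1.22 and 2.13 (adjusted p = 0.0633, 0.0650 and 0.107 with an estimated correlation). The smooth muscle actin Acta2 stood at 5.21 ± 1.37, adjusted p = 0.251, and DESeq2 called it. Pdx1, Mafa, Nkx6-1 and Slc2a2 did not pass the edgeR test: Pdx1 stood at 182 ± 16 against 280.3 ± 52.6 CPM (−0.62 ± 0.17, adjusted p = 0.167; 0.0482 by DESeq2, and 0.0277 to 0.821 over all alternatives), Mafa at −0.61 ± 0.21, adjusted p = 0.329, Nkx6-1 at −0.46 ± 0.15 and Slc2a2 at −0.37 ± 0.16. The beta cell list median was −0.12 with 5 of 28 lower over the list alone (adjusted p = 0.268 with an estimated correlation). The alpha cell list median was −0.24 (adjusted p = 0.0862 with an estimated correlation). Slc7a2 stood at −0.53 ± 0.18. Ins1 stood at 0.21 ± 0.31 and Ins2 at −0.03 ± 0.27. Fibroblast genes took 0.00672 to 0.0396% of counts on laminin-421 (exact permutation p = 0.200 against laminin-521). The count of 22 was 8, 19 and 49 without replicates A, B and C on laminin-421 and 40, 6 and 55 without A, B and C on laminin-521, and fell to 0 with only the 6 libraries in the fit. Dnm3 and Lamb2 kept their calls with each library left out, but with FPKM values both were lost (adjusted p = 0.669 and 0.564), as were Col12a1 and Myof (0.101 and 0.215), and with a pseudocount of 0.1 Tgfb3 (0.150). Without the 3 libraries that stood apart Col12a1, Myof and Tgfb3 lost theirs (0.116, 0.106 and 0.379). Thbs1 and Tgfb3 lost theirs without A or B on laminin-421 (adjusted p = 0.105 and 0.070 for Thbs1, 0.0683 and 0.070 for Tgfb3), as did Col12a1 (0.0683 and 0.0709). Without B on laminin-521 Col12a1, Tgfb3 and Myof lost theirs (0.0979, 0.307 and 0.0799).

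Between laminin-421 and laminin-111 at day 12 no gene passed the edgeR test, with 1418 genes at an unadjusted p under 0.05, 9.31% of genes without overlap, a smallest adjusted p of 0.149, and 40 genes called by DESeq2. Pdx1 stood at 0.23 ± 0.17, adjusted p = 0.816, Mafa at 0.39 ± 0.21, adjusted p = 0.695, Ins1 at −0.16 ± 0.31 and Ins2 at −0.33 ± 0.27. The fibroblast median was 1.21 (adjusted p = 0.720 with an estimated correlation) and the alpha cell median 0.44 (adjusted p = 0.380 with an estimated correlation), and the other 4 lists called with a preset correlation were lost as well. Without replicate C on laminin-111 or replicate C on laminin-421, 4 genes each were called.

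Each coating was also set against uncultured islets, the question being whether the change on culture depended on the coating. Pdx1 rose on all 3 coatings at both days, by 1.2 and 1.15 on laminin-521 at days 3 and 12, 1.24 and 1.77 on laminin-421, and 1.31 and 1.54 on laminin-111. Mafa rose by 1.14 and 1.09, 1.28 and 1.69, and 1.37 and 1.31, and Nkx6-1 by 1.18 and 1.02, 1.13 and 1.49, and 1.11 and 1.39, in the same order. Hspa5 changed by −2.22 and −2.41, −2.31 and −2.19, and −2.33 and −2.29. Genes changed on laminin-521 numbered 2825 at day 3 (1309 higher, 1516 lower) and 3070 at day 12 (1403 and 1667), on laminin-421 2606 (1221 and 1385) and 3497 (1647 and 1850), and on laminin-111 2841 (1331 and 1510) and 3400 (1578 and 1822). Sides of 3 did not overlap in 30.8% to 35.8% of genes, against 10% by chance. With FPKM values Mafa and Nkx6-1 missed the threshold on every coating and day except laminin-421 at day 12, with adjusted p from 0.0648 for Nkx6-1 on laminin-111 at day 12 to 0.339 for Mafa on laminin-521 at day 3.

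The test of the laminin by day interaction asked directly whether the change from day 3 to day 12 differed among coatings. It called 5 genes, and in each the mean rose from day 3 to day 12 on laminin-521 and fell on the other coatings. The small heat shock protein Cryab went from 0.188 ± 0.163 to 5.17 ± 3.27 CPM on laminin-521, while it stood at 0.194 on laminin-421 and at 0 on laminin-111 at day 12 (adjusted p = 0.00762). The phospholipid-binding protein Anxa3 went from 1.98 ± 1.68 to 11.7 ± 11.7 CPM (adjusted p = 0.00900), Col12a1 from 2.31 ± 1.75 to 38.1 ± 42.6 (adjusted p = 0.00900) and the netrin receptor Unc5b from 10.2 ± 3.08 to 34.0 ± 21.4 (adjusted p = 0.0166). Lamb2 went from 4.04 ± 1.56 to 11 ± 14.7 CPM on laminin-521 and from 4.17 ± 2.49 to 0.0782 ± 0.0906 on laminin-421 (adjusted p = 0.0332). For Anxa3, Col12a1 and Lamb2 the SD on laminin-521 at day 12 was at least as large as the mean. The rise of these means therefore need not hold in each library. At day 3 the means were already lower on laminin-521 than on laminin-421 and laminin-111, where they were 4.02 and 2.29 CPM for Cryab, 4.69 and 4.58 for Anxa3, 7.62 and 9.91 for Col12a1, and 20.0 and 22.9 for Unc5b, so part of the interaction lies in the day 3 values, although no gene was called between coatings at day 3. For Pdx1 the interaction had an adjusted p of 0.789 and for Ins1 of 1.00. The count of 5 was 0 and 2 without replicates C and A on laminin-521 at day 3, 3 without B, and 19 and 36 without A and C on laminin-521 at day 12. It was 9 and 18 without B and C on laminin-111 and 10, 13 and 8 without A, B and C on laminin-421 at day 12, and DESeq2 called 94. With the replicate letter as a block it was 8, the 5 genes included. With FPKM values Anxa3, Col12a1, Unc5b and Lamb2 lost their calls (adjusted p = 0.538, 0.414, 0.414 and 0.682), with only the cultured libraries in the fit Col12a1 and Lamb2 did (0.0526 and 0.0691), and without the 3 libraries that stood apart all 5 did (0.0660, 0.248, 0.0660, 0.296 and 0.949 for Cryab, Anxa3, Col12a1, Unc5b and Lamb2). Without replicate C on laminin-521 at day 3 all 5 genes lost their calls, with an adjusted p of 0.0703 for Cryab, 0.0703 for Anxa3, 0.0871 for Col12a1, 0.163 for Unc5b and 0.174 for Lamb2. Without A of the same group it was 0.0660 for Anxa3, 0.145 for Col12a1 and 0.0806 for Lamb2, and without B 0.0921 for Unc5b and 0.112 for Lamb2. Without replicate B on laminin-521 at day 12 it was 0.0976 for Anxa3, 0.165 for Unc5b and 0.251 for Lamb2. Lamb2 also missed the threshold without A or C on laminin-421 at day 12 (0.0585 and 0.0730), without A or C on laminin-421 at day 3 (0.0584 and 0.0852) and without A or C on laminin-111 at day 3 (0.0527 and 0.0503).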

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

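The tests of list-level differences between coatings and of these without single libraries, of splits within letters, of acinar RNA, of a few genes taking most counts, and of a changed share of endocrine cells were chosen only after the results were seen.

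A difference between coatings in the change from day 3 to day 12 was found for 5 genes and for 6 lists. By the interaction test the adjusted p was 0.00762 for Cryab, 0.009 for Anxa3 and for Col12a1, 0.0166 for Unc5b and 0.0332 for Lamb2. The log2 change from day 3 to day 12 on laminin-521, laminin-421 and laminin-111 was 4.0, −2.17 and −2.08 for Col12a1 and 1.73, −0.79 and −1.17 for Unc5b. On laminin-521 and laminin-111 it was 2.54 and −1.63 for Anxa3 and 1.45 and −1.80 for Lamb2. For Anxa3, Col12a1 and Lamb2 the SD of the CPM on laminin-521 at day 12 was at least as large as the mean. On laminin-421 Anxa3 went from 4.69 to 0.153 CPM and Lamb2 from 4.17 to 0.0782 CPM, where 3 counts are 0.137 to 0.177 CPM, so no fold is given. Cryab was at 0 in all libraries of laminin-111 at day 12 and is given as CPM in the report. Of 100 splits that exchange coatings among the libraries of a day only 1, the real one, called as many as 5 genes, and the highest other called 3. These splits ignore the replicate letters, and of 100 splits that exchange coatings only among libraries of the same letter and day, 1, the real one, called as many, with 4 as the highest other. Either kind of split undoes any difference between coatings along with the interaction. The splits thus argue against chance in the absence of any coating effect, at that level and for libraries taken as independent. They cannot exclude chance for the interaction alone. With single libraries left out the interaction called from 0 genes, without replicate C on laminin-521 at day 3, to 36, without replicate C on laminin-521 at day 12, and without the 3 libraries that stood apart it called 2, none of them among the 5. With FPKM values Anxa3, Col12a1, Unc5b and Lamb2 lost their calls (adjusted p = 0.538, 0.414, 0.414 and 0.682), and over all alternatives the adjusted p was 2.74e-09 to 0.0703 for Cryab, 1.91e-07 to 0.538 for Anxa3, 6.10e-17 to 0.448 for Col12a1, 5.58e-08 to 0.423 for Unc5b and 6.40e-07 to 0.949 for Lamb2.

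Lists whose change differed between laminin-521 and laminin-111, with an estimated correlation, were the fibroblast and stellate list (fitted median difference of the log2 changes 5.68, adjusted p = 0.018) and matrix and basement membrane (4.21, adjusted p = 0.00978). Further ones were laminin receptors and adhesion (0.44, adjusted p = 0.018), YAP and TEAD targets (2.68, adjusted p = 0.00792), mesenchymal transition (3.57, adjusted p = 0.0132) and TGF-beta targets (1.52, adjusted p = 0.0132). Between laminin-521 and laminin-421 they were matrix and basement membrane (3.31, adjusted p = 0.0451), YAP and TEAD targets (2.1, adjusted p = 0.0332) and TGF-beta targets (1.98, adjusted p = 0.0479), and the fibroblast list missed the threshold (3.70, adjusted p = 0.124). At day 3 the summed CPM were lower on laminin-521 than on laminin-421 and laminin-111, at 493 ± 164.3, 762 ± 458.4 and 990.3 ± 610.9 for the fibroblast list and 413 ± 111.2, 606 ± 204.5 and 703 ± 236.8 for the matrix list (mean ± SD, n = 3), so the differences of the changes include these lower day 3 values. Without replicate B on laminin-521 at day 12 the median differences against laminin-111 were 3.33 for the fibroblast list, 2.57 for matrix, 0.31 for adhesion, 2.17 for YAP and TEAD, 1.63 for mesenchymal transition and 1.15 for TGF-beta, and against laminin-421 1.58 for matrix, 1.5 for YAP and TEAD and 1.08 for TGF-beta, and all 9 were still called. With each of the 18 cultured libraries left out in turn, all 6 lists stayed called against laminin-111. Against laminin-421 none of the 3 was called without A, B or C on laminin-421 or B on laminin-111 at day 12, or without C on laminin-421, C on laminin-111, or A or C on laminin-521 at day 3. Only 2 were called without A on laminin-111 at day 12 or A or B on laminin-421 at day 3, and 1 without A or B on laminin-111 at day 3. These lists share members, 6 between the fibroblast and mesenchymal transition lists, so they are not independent.

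The first pattern weighed, the higher fibroblast and matrix RNA on laminin-521 at day 12, was tested for a single library as its source by leaving out replicate B on laminin-521, which held 0.549% of counts in fibroblast genes. Against laminin-111 the list median was then 2.31 (quartiles 1.90 to 3.27; 90.0% of members above 0) in place of 4.41 (quartiles 4.01 to 5.36), which argues against that library as the whole source. Against laminin-421 it was 1.28 (quartiles 0.34 to 2.17) in place of 3.28, with 83.3% of members above 0. This met the bounds set beforehand, a median of at least 1 and more than 3 in 4 members above 0, but not by more than the spread, as the lower quartile lies below 1, so a real difference and the effect of that library cannot be told apart. A lower share of endocrine cells would raise the markers of other cells alike. Against laminin-111, with replicate B kept, the macrophage median was 1.01 (quartiles 0.28 to 1.53) and the endothelial median 0.64 (quartiles −0.75 to 2.48). With replicate B kept these argue against a lower endocrine share as the whole source. The fibroblast quartiles without replicate B (1.90 to 3.27) still lie above the macrophage ones but overlap the endothelial ones, so the endothelial list does not decide it. Endothelial genes took only 0.00226% of counts on laminin-111 and 0.00375% on laminin-521 at day 12. On laminin-521 at day 12 replicates A and C (0.0598% and 0.0392%) lay within the day 3 range of that coating (0.0332% to 0.0671%). Fibroblast genes meanwhile went from a mean of 0.1025% to 0.0097% on laminin-111 and from 0.0778% to 0.0239% on laminin-421. Apart from replicate B, the gap thus came with a fall on the other coatings rather than a rise on laminin-521. A candidate explanation is more fibroblasts, or more matrix RNA per cell, on laminin-521 than on the other coatings at day 12. Neither this nor the number of stromal cells carried into each well was tested.

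The second pattern weighed is the lower level of interferon, immediate early and unfolded protein response genes at day 3 than at day 0. RNA of acinar cells was most abundant in uncultured islets, but over these 3 libraries the slope of log2 CPM on log2 acinar share had a median of −0.0520 in the 65 fallen members (quartiles −0.23 to 0.17), against 0.95 for the acinar list (quartiles 0.88 to 1.08). The acinar list makes up that share, so its own slope was fixed by construction. Over only these 3 libraries, the values argue against acinar RNA as the whole source. The median slope was −0.30 for the immediate early and −0.11 for the unfolded protein response genes. For the interferon genes it was 0.18 (quartiles 0.08 to 0.25, 84% above 0), so acinar RNA as part of their source is not excluded. If a few genes took most counts all other genes would fall alike, whereas with library totals alone the median of the other tested genes was 0.21 (quartiles −0.36 to 0.73), against −3.12, −2.56 and −1.01 for the 3 lists (quartiles −1.27 to −0.57 for the last), which argues against this as the source. Islet isolation and handling before RNA was taken coincide with day 0 and cannot be told apart from a response to culture, which may hold for the acinar loss too, and sequencing batches, which the labels do not assign to libraries, were not tested.

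The third pattern weighed is the lower level of endothelial genes at day 12 than at day 3. A rising share of endocrine cells would lower all other cell types alike. The macrophage median was 0.22 (quartiles −0.14 to 0.38), against −3.61 for the endothelial list (quartiles −4.27 to −2.39, or −3.07 with members at 0 in a whole group at their bound). The fibroblast median was −0.735 (quartiles −1.46 to 0.01, or −0.57 at the bound), but it averages coatings that moved apart. On laminin-111 the fibroblast share of counts went from 0.1025% to 0.0097%, much as the endothelial share did there (0.02205% to 0.00226%). On laminin-421 the fibroblast share went from 0.0778% to 0.0239%, and on laminin-521 from 0.05015% to 0.216%, with 0.549% in replicate B. The macrophage values argue against a rising endocrine share as the whole source, while the fibroblast values on laminin-111 do not. A loss of endothelial cells over culture is a candidate explanation that was not tested apart from lower expression per cell or from sequencing batch.

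In other splits of the same libraries, 1 of 100, the real one, called as many genes in each comparison between days. The counts were 4191 for day 3 against day 0 (highest other 160) and 4793 for day 12 against day 0 (highest other 626). For day 12 against day 3 the count was 270 (highest other 59). At that level this argues against a random allotment of independent libraries as the source of these counts. The splits treat the libraries as independent, and whether they came from separate mice is not stated. Differences between islet preparations or sequencing batches are therefore not excluded. Splits of 3 against 3 number 10, too few for a share under 0.05. For laminin-521 against laminin-111 at day 12 the real split called 8 and the highest other 1, and against laminin-421 22 and 19, where 1 split each reached the real count. Of the 4 splits that part all 3 same-letter pairs of laminin-521 and laminin-421 at day 12, the real one called 22 and the others 1, 0 and 1, and the split with 19 held both C libraries on one side and both B libraries on the other. For laminin-421 against laminin-111 at day 12 it was 0 and 3, and at day 3 it was 0 and 0 for laminin-521 against laminin-111 and against laminin-421 and 0 and 1 for laminin-421 against laminin-111, where 10 of 10 splits called as many. Against day 0 the highest other called 0, 1 and 0 on laminin-521, laminin-421 and laminin-111 at day 3 (real values 2825, 2606 and 2841) and 3, 2 and 0 at day 12 (3070, 3497 and 3400).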

How the results depend on the processing

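The fits without 3 libraries that stood apart and with replicate C as the only uncultured library were chosen only after the data were seen. No named gene reversed its direction while called, and where a result was lost the cause was not tested unless stated.

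For day 3 and day 12 against day 0 the counts of changed genes stayed within 1.5 times 4191 and 4793 with DESeq2, RLE factors, library totals, either low-count filter, gene classes left out, the replicate block and only the libraries compared. With FPKM values and a pseudocount of 1 they were 2709 and 2898, with 0.1 2531 and 2876, and with replicate C as the only uncultured library, a fit with fewer samples, 2422 and 2675. For day 12 against day 3 DESeq2 called 570, no filter 650, and FPKM 105 and 150. For single coatings against day 0 at days 3 and 12, FPKM with a pseudocount of 1 called 1816 and 1891 on laminin-521, 1520 and 2121 on laminin-421 and 1672 and 1999 on laminin-111, and with 0.1 1619 and 1755, 1345 and 2100, and 1498 and 1952. With replicate C as the only uncultured library they were 1767 and 1797, 1810 and 1892, and 1840 and 2038, the lone library being assumed to vary like the other groups, and with only the libraries compared 1973 on laminin-521 and 1929 on laminin-421 at day 12.

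For laminin-521 against laminin-111, laminin-521 against laminin-421 and laminin-421 against laminin-111 at day 3, DESeq2 called 8, 9 and 0, no filter 73, 91 and 42, and FPKM with a pseudocount of 1 1, 1 and 2. With only the libraries compared 6 were called for the first of these. At day 12 DESeq2 called 174, 261 and 40, no filter 307, 308 and 102, at least 10 CPM 5, 7 and 0, FPKM with a pseudocount of 1 4, 15 and 1, and with 0.1 2, 9 and 2. Without the 3 libraries that stood apart the counts were 4, 7 and 1, and with only the libraries compared 1, 0 and 0, where the spread is estimated from fewer libraries. For the interaction DESeq2 called 94, no filter 362, at least 10 CPM 2, FPKM 1 and 2 with Cryab alone of the 5 genes, the fit without 3 libraries 2 with none of the 5, and the fit of only the cultured libraries 3, all among the 5.

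With the replicate letter as a block, 2 genes were called for laminin-521 against laminin-111 and 2 against laminin-421 at day 3, 4 and 23 at day 12, and 8 for the interaction. With this block Thbs1 (adjusted p = 0.0718), Mylk (0.0900), Col12a1 (0.0900) and Peak1 (0.0733) missed the threshold against laminin-111 at day 12, and Ins1 for day 12 against day 0 (0.0566), and the block changed the call of no other gene named here. At the preset correlation it changed 5 list calls, all between coatings.

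With each library left out in turn, calls ran from 3231 to 4135 for day 3 against day 0, 3803 to 5170 for day 12 against day 0, 210 to 392 for day 12 against day 3 and 0 to 36 for the interaction. They were 0 to 0, 0 to 0 and 0 to 0 for the coating pairs at day 3 and 2 to 49, 6 to 55 and 0 to 4 at day 12. Against day 0 they were 1976 to 2379 and 2313 to 2680 on laminin-521, 1866 to 2345 and 2615 to 3075 on laminin-421 and 2025 to 2462 and 2504 to 2876 on laminin-111 at days 3 and 12.

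For lists, 14 calls at day 3 against day 0 became 9 with an estimated correlation, 17 at day 12 became 12, and 14 for day 12 against day 3 became 2 (8 by fry). At day 3 the 13, 14 and 4 list calls of the coating pairs all became 0 and 0 by fry, and at day 12 15, 13 and 6 calls became 6, 0 and 0 (6, 7 and 0 by fry). Against day 0 they became 10 and 9 on laminin-521, 9 and 12 on laminin-421, and 9 and 12 on laminin-111 at days 3 and 12. The share of hormone genes without mitochondrial genes in the total was 11.7% on laminin-521 at day 3 and 12.7% on laminin-111 at day 12, and that of macrophage genes 0.0335% on laminin-421 at day 3, and the other shares moved by less than the spread between replicates.

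Of the values of named genes under the alternatives set beforehand, leaving out a library apart, 415 of 423 kept their side of the threshold and direction for day 3 against day 0, 262 of 272 for day 12 against day 0 and 199 of 214 for day 12 against day 3. The same held for 121 of 147 and 113 of 137 for laminin-521 against laminin-111 and laminin-421 at day 12, and 56 of 66 for the interaction. Against laminin-421 FPKM with a pseudocount of 1 ended the calls of Dnm3 (adjusted p = 0.669), Lamb2 (0.564), Col12a1 (0.101) and Myof (0.215). Hormone, acinar and mitochondrial genes gave no value where these classes were left out, nor did Mylk, Lamb2, Cryab and Anxa3 at 10 CPM or more. Sequencing depth limits a single library to a floor of 0.122 to 0.278 CPM, and Cryab, Lamb2 and Anxa3 lay near it in part of the groups.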

Other observations

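The tests of gene families, formed by the start of the gene symbol, were chosen only after the data were seen, and 262 families were tested in each comparison. For day 3 against day 0, 12 of 13 genes of the interferon-inducible Ifi family fell (adjusted p = 0.0379 with an estimated correlation) and 7 of 15 Klf transcription factors (0.0379). The fixed lists hold 1 of these Ifi genes and 4 of the Klf genes. The Gbp family of guanylate-binding proteins fell in 9 of 10 and the Dusp phosphatases in 10 of 21, where 1 rose, and both were called only at the preset correlation (0.323 and 0.323 with an estimated correlation). For day 12 against day 0, 75 of 362 zinc finger genes of the Zfp family rose and 19 fell (0.209 with an estimated correlation), and 10 of 34 histone genes rose (0.264).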
